A study of Mus musculus with 11 samples.

How the data were processed

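Mouse bead arrays of 11 tumour samples were analysed: 3 from WT hosts given PBS, 3 from WT hosts given doxorubicin (DX), 3 from Fpr1-/- (KO) hosts given PBS and 2 from KO hosts given DX. Per the labels, the tumours were subcutaneous fibrosarcomas in C57BL/6 mice, injected into the tumour and taken 2 days later. The number of the tumour in the source names rises by 1 from each sample to the next, which was taken as a spreadsheet fill and all samples as 1 tumour line. If the lines differed, every group difference would hold that difference as well. The deposited probe file holds an intensity for each of 45281 probes on each array, linear and not normalized per the file headers. Beside each intensity the same file holds, per the file headers, a detection p-value against negative controls. The second deposited table holds log2 values of 19215 probes, processed by the authors, with near-equal medians on all arrays (8.39 to 8.40). Partek is the only tool named in the submitters' processing notes, and its steps are not stated there.

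The intensities were used for the main results, since their processing could be followed from the start. In limma 3.58.1 (R 4.3.3), neqc inferred the background from the detection p-values, subtracted it, added an offset of 16, quantile normalized and took log2. A probe was kept with a detection p under 0.05 on at least 2 arrays, which left 20433 probes. The filter dropped 244 named probes. Symbols came from the supplied annotation, where 16496 probes carried 1 symbol, 9 carried several and 2710 of the table's 19215 probes carried none. Of the named probes, 16479 were matched to the current gene tables by Entrez number. Each gene was represented by its brightest kept probe, giving 10623 genes, of which 3874 had several kept probes. The 4181 kept probes without a single symbol were tested apart. The annotation named only probes of the authors' table, so the genes tested were bounded by the authors' own choice of probes, also where no filter was applied. No probe was named Fpr1, so the planned exact permutation test of Fpr1 in KO against WT could not be run and Fpr1 itself was not analysed here. A gene without a named probe may still be on the array and detected.

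One limma model gave each of the 4 groups its own mean over all 11 arrays, with 7 residual degrees of freedom and 4.04 prior degrees of freedom. Moderated t tests (eBayes) were run for 7 contrasts: DX minus PBS in WT and in KO, the difference of these, KO minus WT in PBS and in DX, and the 2 averaged effects. Every p-value of a gene in these texts is from limma unless another test is named. Adjusted p-values are Benjamini and Hochberg, with a threshold of 0.05 within each contrast. A gene was said to rise or fall only past that threshold. A fold change is given as "at least" where no probe of the gene was detected in 1 of the 2 groups, with the lowest detected signal in place of that group. It was not computed for the averaged contrasts. Groups were called non-overlapping when every array of 1 group lay above every array of the other, which chance alone gives for 10% of genes with 3 arrays against 3.

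Gene groups were 25 fixed lists written before the data were examined, tested with camera at an inter-gene correlation of 0.01. Each list was also tested with the correlation estimated from the data and with fry. The counts "adjusted over the list alone" correct the gene p-values over the members of 1 list only. Named genes followed a rule also set before the data were examined. In the 2 DX contrasts the 10 largest rises and 10 largest falls past the threshold with non-overlapping groups were named, filled by smallest p, and in the other contrasts 5 and 5. For each list past the camera threshold the 4 members with the smallest p in its direction were added. A fixed set (Fpr1, Fpr2, Anxa1, Cdkn1a, Mdm2, Mki67, Cd8a, Cd3e, Ifng, Gzmb, Itgax, Cxcl10, Ccl2 and S100a8) was named wherever measured. Fpr1, Mki67, Cd8a and Gzmb were not among the measured genes, which does not show that they were undetected.

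The alternatives chosen before the data were examined were no background correction, median scaling, the authors' table, no filter or a stricter one (detection p under 0.01 on at least 3 arrays), the mean of a gene's probes, every probe, only the 2 or 4 groups of the contrast, the BeadChip as a fixed or random block, the replicate number as a block, array weights, trend with robust eBayes, and leaving out each array. Added after the data had been seen were the mean of the muscle genes as a covariate, the removal of the 2 arrays with Eif2s3y signal, the authors' table without its 2 averaged columns, and no background correction with a chip block on the probes of that table. The 11 arrays lay on 5 BeadChips. Chip 1 held KO PBS 1 and WT DX 1, chip 2 KO PBS 2 and WT PBS 1, chip 3 WT DX 2 alone, chip 4 KO DX 1, KO DX 2 and WT PBS 2, and chip 5 KO PBS 3, WT DX 3 and WT PBS 3. Within-chip differences could be taken for DX in WT on chip 5 and for KO minus WT in PBS on chips 2 and 5. The model with the BeadChip as a fixed block left 3 residual degrees of freedom, so a call can end there without a change of size.

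The code was tested on simulated data of the same group sizes, 5 simulations of 10623 genes. A log2 change of 1 was recovered for 80.0% of genes in WT and 73.4% in KO, and a change of 2 for 99.0% and 98.4%. Over the 5 simulations 500 genes were changed by each size, with normal noise, and many changed genes ease the adjusted threshold. In the real KO contrast Cxcl2 at 2.59 did not pass in limma (adjusted p = 0.0726). The simulated shares are therefore no measure of what the real contrasts could detect. False calls made up 5.08% of WT calls and 5.49% of KO calls. A shift of 0.3 over 30 genes was found in 5 of 5 lists and 0 unchanged lists were called, though the simulated genes were independent of each other. The figures were drawn with matplotlib 3.10.9. The labels do not say whether the samples are separate animals, so the p-values measure the spread between these samples.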

Results

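The 11 tumours gave arrays with similar shares of detected probes, but both arrays of chip 2 were dimmer than the rest. Between 16169 and 18221 of the 45281 probes were detected per array (35.7% to 40.2%), and the median signal ran from 110 to 169. On chip 2 it was 110 for WT PBS 1, which also had the fewest detected probes, and 118 for KO PBS 2. The other arrays lay at 151 to 169. Chip 2 held no DX array. Arrays of 1 group correlated at 0.976 to 0.992, and no 2 arrays held identical values. The number of arrays, 3 per group and 2 for KO DX, limits the precision of every change given here.

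In WT hosts, some genes of neutrophils, their chemokines, the type I interferon response and the p53 response rose within 2 days of DX. Of these 4 lists only that of p53 targets kept its call with an estimated correlation. Some genes of skeletal muscle rose beside them. Haemoglobin genes, the transferrin receptor gene and Dlk1 fell. Of 10623 genes, 66 passed the threshold in limma, 59 rising and 7 falling, while 1245 had an unadjusted p under 0.05 (531 expected by chance). Of all genes, chance alone would leave 10% without overlap between 3 arrays and 3.

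The largest rise was that of Ppbp, which encodes a platelet and myeloid chemokine, at least 18.1-fold (adjusted p = 0.000397). Cxcl2, a chemokine that draws neutrophils, rose by 3.79 (adjusted p = 0.000611) and Cxcl1, of the same receptor family, by 1.70. S100a9 and S100a8, the calprotectin subunits of neutrophils and monocytes, rose by 3.17 and 2.72. Hcar2 (a niacin receptor of myeloid cells) rose by 2.09, Lcn2 (lipocalin, an iron-binding neutrophil protein) by 2.07, Hdc (the histamine-forming enzyme) by 2.10, Cstdc4 (a stefin protease inhibitor) by 2.18 and Ifit1bl1 (an interferon-induced protein) by 2.10. Ccl3 and Ccl4, macrophage chemokines, rose by 2.09 and 1.52. Cdkn1a, the p53 target that halts the cell cycle, rose by 1.44 (SE 0.159, adjusted p = 0.00253). The falls were Hbb-bt by 2.28 and Hbb-bs by 2.13 (beta globins), Dlk1 by 1.29 (a Notch-like surface protein), Tenm3 by 0.94 (a teneurin adhesion protein), Tfrc by 0.87 (the transferrin receptor) and Hectd2 by 0.86 (a ubiquitin ligase). Engase (a glycan-trimming enzyme) fell by at least 1.46-fold.

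Among the fixed genes, Cxcl10 at 0.80 (adjusted p = 0.149), Ccl2 at 0.58, Fpr2 at 0.61, Mdm2 at 0.28, Ifng at 0.24, Cd3e at -0.031, Anxa1 at -0.10 and Itgax at -0.23 did not pass in WT. With the BeadChip as a block 69 genes passed, 26 of them among the 66. In the chip-block model Ppbp kept its call (adjusted p = 0.0359), its size not exact since its probe was detected on no PBS array. Cdkn1a lost its call (adjusted p = 0.0543) with its size little changed, at 1.48 beside 1.44 without the block. Within chip 5, the 1 chip with both WT groups, Cxcl2 differed by 4.17, S100a9 by 3.55 and S100a8 by 3.15. Ppbp was also higher in WT DX there, its size again not exact.

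**Figure D1:**
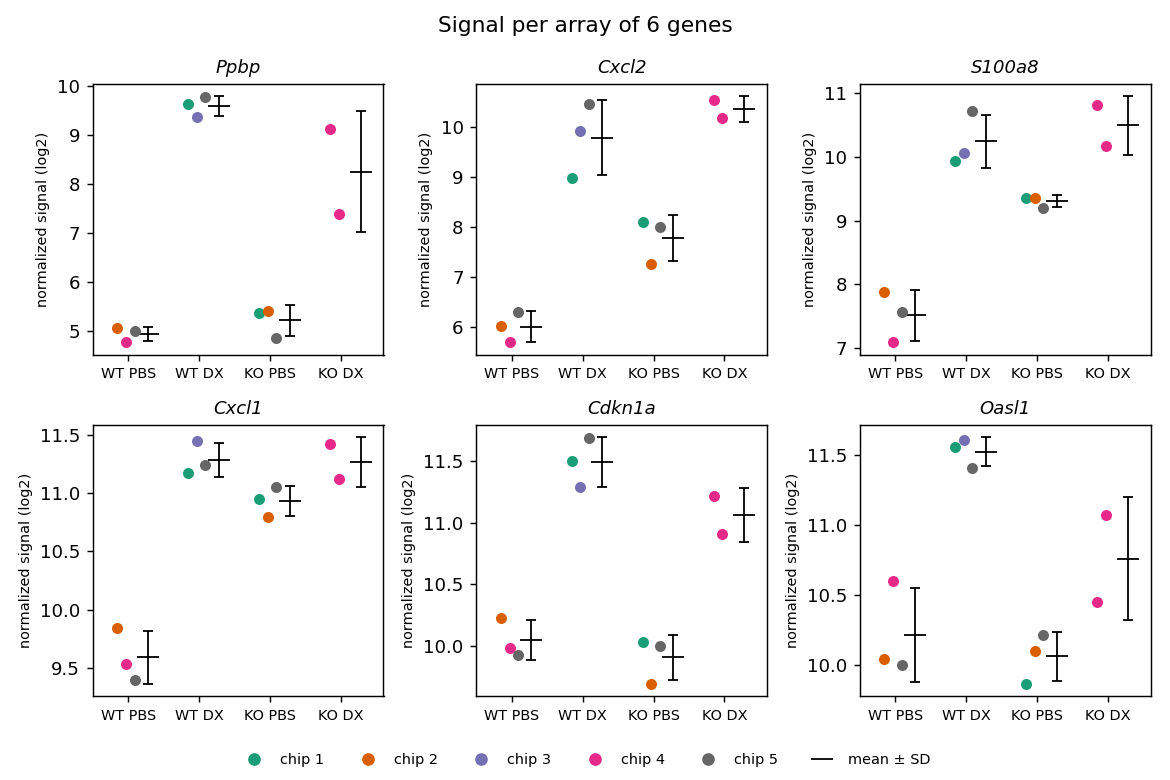
Normalized log2 signal (vertical) of 6 genes in the 4 groups (horizontal), 1 point per array coloured by chip, with mean and SD beside the points. Ppbp rose from below detection to 9.60 in WT hosts, and Cxcl1 stood at 9.59 in WT PBS but 10.93 in KO PBS.

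Ppbp, Cxcl2, S100a9, S100a8, Ifit1bl1, Hcar2, Cdkn1a, Cxcl1 and Ccl4 passed in WT whichever 1 of the 11 arrays was left out, and Ccl3 lost its call only without WT DX 3. The other named genes lost theirs without WT DX 1, WT DX 3 or WT PBS 3, all but Dlk1 also without KO PBS 3, and all but Hbb-bs and Oasl1 also without WT PBS 2. Lcn2, Hbb-bt, Hbb-bs, Tfrc, Hectd2, Ccr2, Myl1, Tnni2, Tnnt3 and Trp53inp1 further lost it without KO PBS 1. Leaving out KO PBS 2 ended the calls of Lcn2, Fcgr1, Myl1, Tnni2, Tnnt3 and Trp53inp1. Lcn2, Hbb-bt, Hbb-bs, Fcgr1 and Trp53inp1 lost theirs without KO DX 1 or KO DX 2, and the first 4 of these and Tnnt3 without WT PBS 1. The count of 66 moved to 39 without KO PBS 1, 16 without KO PBS 3, 14 without WT DX 1, 233 without WT DX 2, 10 without WT DX 3, 24 without WT PBS 2 and 12 without WT PBS 3. With the mean of the muscle genes as a covariate, a model chosen after the data had been seen, limma gave 0 genes in WT and 589 at an unadjusted p under 0.05. Of the variance of that mean 0.793 lay between groups, so the covariate largely overlapped with the groups and the adjusted changes are imprecise.

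The chemokine and inflammatory cytokine list held 35 measured genes, of which 8 rose (Ppbp's relatives Cxcl1 and Cxcl2, Ccl3 and Ccl4 among them), 0 fell and 27 did not pass. Adjusted over the list alone 20 rose and 1 fell. Its median was 0.80 (camera adjusted p = 1.16e-22, adjusted p = 0.0534 with an estimated correlation). In the type I interferon list Oasl1 by 1.32 (an oligoadenylate synthetase-like antiviral protein) and Ifi205 by 1.29 (a nuclear DNA-binding protein) rose, 33 did not pass, and all 35 were up at a median of 0.62. Rsad2 (viperin) at 1.01 (adjusted p = 0.0552) and Mx1 (an antiviral GTPase) at 1.44 (adjusted p = 0.0745) did not pass alone. Of 11 neutrophil genes, S100a8, S100a9 and Hdc rose, 8 did not pass, and the median was 1.07. Retnlg (resistin-like gamma) at 2.18 did not pass (adjusted p = 0.0676). With an estimated correlation the interferon list had adjusted p = 0.115 and the neutrophil list adjusted p = 0.0912. Adjusted over the list alone 21 interferon genes and 8 neutrophil genes rose.

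Moving in the same arrays, 4 of 18 skeletal muscle genes rose in WT: Mylpf by 1.52, Myl1 by 1.32 (myosin light chains), Tnni2 by 1.31 and Tnnt3 by 1.83 (fast troponins). The other 14 did not pass, the median was 1.26, and adjusted p = 0.115 with an estimated correlation. The mean of the list lay 1.44 above its average in WT DX 1, 0.84 in WT DX 3 and 0.36 in WT DX 2. Keratinocyte genes had a median of 0.90 (adjusted p = 0.264 with an estimated correlation), Krt16 (a stress keratin) at 1.45 not passing, and WT DX 3 stood 1.45 above average in both the keratinocyte and the mast cell list. Adipocyte genes had a median of 0.54 (adjusted p = 0.45 with an estimated correlation), Lpl (lipoprotein lipase) at 1.58 and Adipoq (adiponectin) at 1.30 not passing. Mast cell genes had a median of 0.61 and NK cell genes of 0.29, each at adjusted p = 0.615 with an estimated correlation. The 2 red blood cell genes of the lists, whose median was -1.67 (adjusted p = 0.185 with an estimated correlation), did not pass singly, Hba-a1 (alpha globin) standing at -2.25, and WT PBS 3 lay 2.01 above average. Without WT DX 3 the keratinocyte median was 0.15 and its call ended. The NK and mast cell calls ended without WT DX 1, WT DX 3, WT PBS 2 or WT PBS 3, and the adipocyte call without WT DX 3 or WT PBS 3.

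Of 33 p53 targets, Cdkn1a and Trp53inp1 rose, the second (an autophagy and death regulator) by 1.08, and 31 did not pass. This was the only WT list that kept its call with an estimated correlation (adjusted p = 0.036), though its median was 0.09. Ddit4l (an mTOR inhibitor), up by at least 1.44-fold, and Dcxr (a sugar reductase) at 1.23 did not pass alone. Of 21 monocyte and macrophage genes, Ccr2 (the receptor of Ccl2) rose by 1.10 and Fcgr1 (a high-affinity IgG receptor) by 0.93, 19 did not pass, and the median was 0.24 (adjusted p = 0.378 with an estimated correlation). All 33 antigen presentation genes were up, none passing, at a median of 0.18 (adjusted p = 0.541 with an estimated correlation), Cd274 (the PD-L1 ligand) at 1.07 among them. Immediate early genes had a median of 0.19 (adjusted p = 0.0573 with an estimated correlation), Atf3 (a stress transcription factor) at 0.92 and Dusp1 (a MAP kinase phosphatase) at 0.76 not passing. Hypoxia genes had a median of 0.11 (adjusted p = 0.622 with an estimated correlation), with Car9 (a carbonic anhydrase) at 1.08 and Adm (adrenomedullin) at 1.12. That median was -0.016 with the chip block and -0.018 without WT PBS 3, and the call ended without WT DX 2. The antigen presentation call ended without WT PBS 3. With the muscle gene mean as a covariate, chosen after the data had been seen, WT medians turned to -0.17 for antigen presentation (camera adjusted p = 0.00453), -0.046 for monocytes, -0.70 for NK cells (camera adjusted p = 0.00168), -0.50 for mast cells and -0.019 for adipocytes. These tests used the fixed correlation only, and the covariate largely overlapped with the groups.

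The other 11 lists did not pass in WT, with camera adjusted p from 0.0731 to 0.835. Their medians were 0.05 for T cells, -0.04 for B cells, 0.19 for dendritic cells, 0.08 for endothelial cells, -0.16 for fibroblasts and 0.11 for formyl peptide receptors and danger signals. Cell cycle genes stood at -0.07, histones at -0.09, the unfolded protein response at 0.0068, extracellular matrix at 0.03 (Mmp13, a collagenase, rose by 1.01) and oxidative stress at 0.04. The B cell list differed in sign between median and mean. With the chip block 4 of these lists gained a call, T cells at 1.00 (adjusted p = 2.08e-05), endothelial cells at 0.33 (adjusted p = 4.75e-05), dendritic cells at 0.48 (adjusted p = 0.00145) and extracellular matrix at 0.13 (adjusted p = 0.0178), and hypoxia lost its call. Without the block those 4 had adjusted p = 0.622 to 0.694 with an estimated correlation, which was not run with the block. The T cell list lay at -0.71 in WT DX 2, which the block takes out of this contrast, against 0.44 in WT DX 1 and 0.57 in WT DX 3. The chip-block model put chemokines at 1.10, interferon at 0.85, neutrophils at 1.38 and muscle at 1.47. Within chip 5 the medians were 1.24 for chemokines, 1.05 for interferon, 1.65 for neutrophils, 1.49 for muscle, 1.94 for keratinocytes and 2.08 for mast cells. Of the 25 lists 14 passed with camera and 6 with fry. Other splits of the same arrays into 3 and 3 gave a median of 9 with camera, so a list call alone carries little weight.

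**Figure D2:**
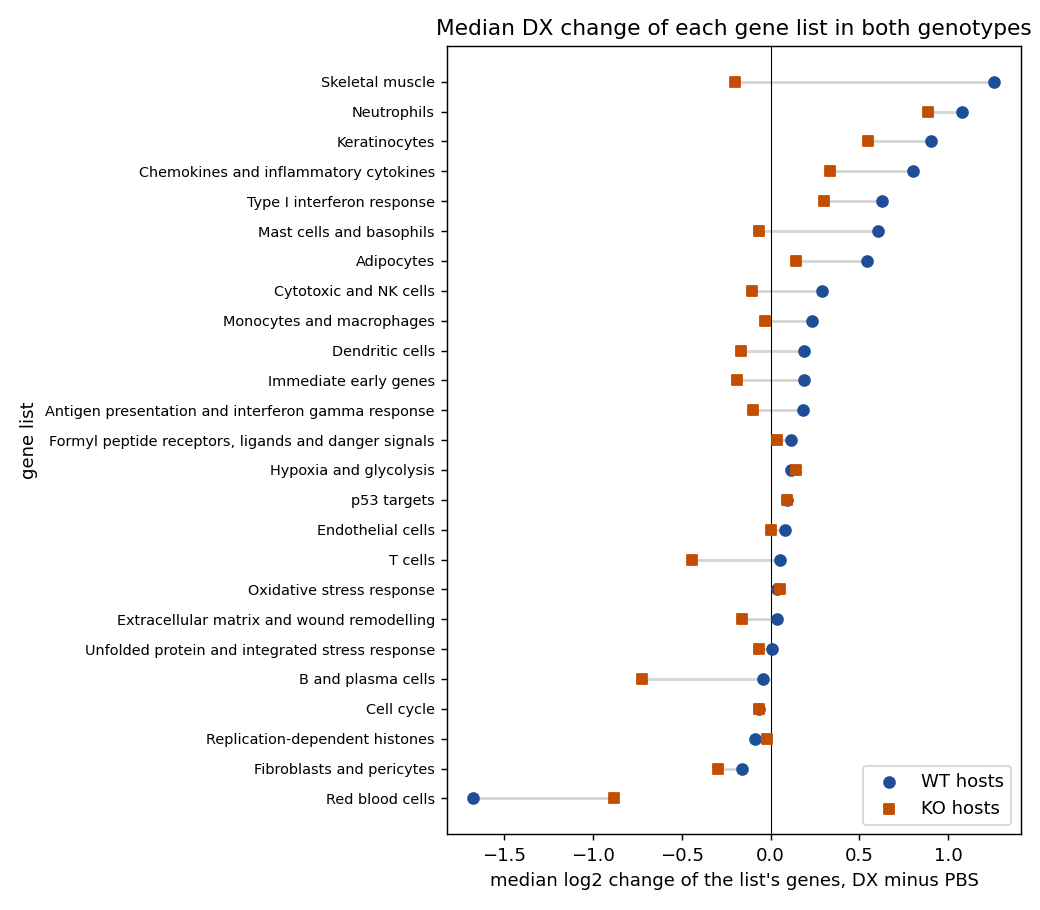
Median log2 change with DX (horizontal) of each of the 25 gene lists (vertical), WT hosts as circles and KO hosts as squares. Skeletal muscle lay at 1.26 in WT and -0.20 in KO, and neutrophils at 1.07 and 0.89.

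In KO hosts no gene passed, yet the genes nearest the threshold were largely those that rose in WT hosts. Chemokines of neutrophils and macrophages, calprotectin and Cdkn1a were up, and Dlk1 was down. Skeletal muscle genes were not up. Limma gave 0 genes past the threshold, with 569 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0726, and with the BeadChip as a block 1 gene passed. That gene was Slc40a1, the iron exporter ferroportin, at 2.34 (adjusted p = 0.213) without the block and 3.48 (adjusted p = 0.0245) with it.

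Ppbp was up, its size not exact since its probe was detected on 0 of 3 KO PBS arrays. Cxcl2 stood at 2.59, Ccl4 at 1.24 and Dlk1 at -1.43, and Csta3 (a stefin) was up by at least 1.3-fold. Each of these genes, Ppbp included, had adjusted p = 0.0726. Cdkn1a stood at 1.16 (adjusted p = 0.0783), S100a9 at 1.55 (adjusted p = 0.213), S100a8 at 1.19 (adjusted p = 0.433), Ccl3 at 1.38 and Plin2 (a lipid droplet coat protein) at 0.83. On the falling side stood Tapbp (tapasin, which loads MHC class I) at -1.23, St6galnac4 (a sialyltransferase) at -0.68, Mfap4 (a microfibril protein) at -1.51 and Pi16 (a fibroblast surface protein) at -1.32. The other kept probe of Tapbp stood at only -0.17, and the probes of St6galnac4 ran from -0.68 to -0.24. Of the 66 genes called in WT, 58 had the same sign in KO and 34 passed when adjusted over these genes alone. As all contrasts shared 1 estimate of the spread per gene, choosing genes by their WT test also favours passing in KO. The KO change was the smaller in 64 of the 66 genes, as selection on the WT value favours. The median of the 59 that rose was 1.28 in WT and 0.61 in KO. Across all genes, which are not independent, the 2 DX changes correlated at 0.317.

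Of the 25 lists 10 passed with camera in KO hosts, and 0 with fry. Upward were interferon at a median of 0.30, chemokines at 0.33 (both adjusted p = 0.433 with an estimated correlation), neutrophils at 0.89, p53 targets at 0.10 (both adjusted p = 0.337 with an estimated correlation) and hypoxia at 0.14 (adjusted p = 0.798 with an estimated correlation). Adjusted over the list alone 9 of 11 neutrophil genes and 5 of 35 chemokine genes rose. Downward were fibroblasts at -0.29 (adjusted p = 0.337 with an estimated correlation), B cells at -0.72 (adjusted p = 0.433 with an estimated correlation), extracellular matrix at -0.16 (adjusted p = 0.679 with an estimated correlation), antigen presentation at -0.10 (adjusted p = 0.844 with an estimated correlation) and T cells at -0.44 (adjusted p = 0.798 with an estimated correlation). Only Cd79b, Mzb1 and Fcrla were measured for B cells, and their mean lay 1.63 above average in KO PBS 2. It lay at -0.09 in KO PBS 1 and 0.08 in KO PBS 3, and at -0.21 and -0.55 in KO DX. The chip block brought interferon to -0.02 and hypoxia to -0.02, chemokines to 0.05 (adjusted p = 0.983), ended the p53 call as well (0.11, adjusted p = 0.432) and left neutrophils at 0.88 (adjusted p = 0.00682). With the block 8 of the 25 lists passed with camera. The muscle median of -0.20 did not pass. Both KO DX arrays lay on chip 4 with WT PBS 2 and no KO PBS array, so no within-chip value exists for this comparison. The gene count was 2 without KO DX 2 and 1 without WT DX 1 or WT DX 2.

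As lists, most inflammatory genes responded less to DX in KO than in WT hosts with camera at its fixed correlation, but no list passed with an estimated correlation or with fry, and no single gene passed. Skeletal muscle, chemokines, monocytes and antigen presentation had the smallest camera p. With the muscle gene mean as a covariate, chosen after the data had been seen, the median differences turned to 0.0056 for interferon, 0.034 for monocytes, 0.20 for antigen presentation, 0.73 for T cells, 0.86 for NK cells, 0.28 for dendritic cells, 0.47 for mast cells and 0.042 for p53 targets. Of these, T cells (camera adjusted p = 0.00702) and NK cells (camera adjusted p = 0.00155) passed in the opposite direction at the fixed correlation, and no other was run with the covariate. As 0.793 of the muscle mean's variance lay between groups, these turns do not show an opposite effect. Limma gave 0 genes for this difference, with 498 at an unadjusted p under 0.05, fewer than the 531 expected by chance, and a smallest adjusted p of 0.11. The chip block also gave 0, and leaving out KO PBS 1 gave 1.

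Nearest the threshold were Clec2d (a ligand of an NK receptor) at -2.01 (SE 0.265, adjusted p = 0.11), Cxcl1 at -1.36 (adjusted p = 0.567), Mylpf at -1.80 (adjusted p = 0.639), Agpat1 (a lipid acyltransferase) at -1.11 and Myf6 (a muscle transcription factor) at -1.65. Upward were Tmem164 (a membrane acyltransferase) at 1.60, Krit1 (an endothelial junction protein) at 1.09, Terf1 (a telomere-binding protein) at 1.02 and Itfg1 (an integrin-like membrane protein) at 1.80, and the probes of Tmem164 and of Krit1 differed in sign. S100a9 stood at -1.62, S100a8 at -1.53 and Il1b (interleukin 1 beta) at -1.15. Over the 66 genes called in WT alone, a set chosen by its WT change, 26 passed for the difference. Among them were Clec2d (adjusted p = 0.000681), Cxcl1 (adjusted p = 0.00352), Mylpf (adjusted p = 0.00791) and S100a8 (adjusted p = 0.0133). Ppbp passed as well (adjusted p = 0.0287), but its probe was detected on no PBS array, so its difference rests on levels below detection. The difference holds the same WT change that chose the 66 genes, which favours passing. The adjusted p-values over these 66 genes are therefore no valid test of a difference between the hosts.

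Of the lists 15 passed, all downward, and with an estimated correlation none did (adjusted p = 0.177 to 0.565). Chemokines stood at a median of -0.48, 33 of 35 genes down, monocytes at -0.47 (21 of 21 down), neutrophils at -0.44, interferon at -0.25 (29 of 35 down) and antigen presentation at -0.38. Skeletal muscle, moving with them, stood at -1.49, Tnnt3 at -2.37. T cells were at -0.56, B cells at -0.68, NK cells at -0.39, dendritic cells at -0.40 and mast cells at -0.50. The B cell value rests on Cd79b, Mzb1 and Fcrla alone, whose mean stood 1.63 above average in KO PBS 2. Fibroblasts were at -0.21, extracellular matrix at -0.24, immediate early genes at -0.31 and p53 targets at -0.16 although their medians in the 2 hosts were near equal, Sesn2 (a stress-induced sestrin) at -1.12 among them. The interferon call ended without WT PBS 3 and the neutrophil call without KO DX 2 or WT DX 3. With the chip block 19 lists passed, though p53 targets lost their call (-0.18, adjusted p = 0.189), and among other splits of the arrays the median was 8.

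**Figure D3:**
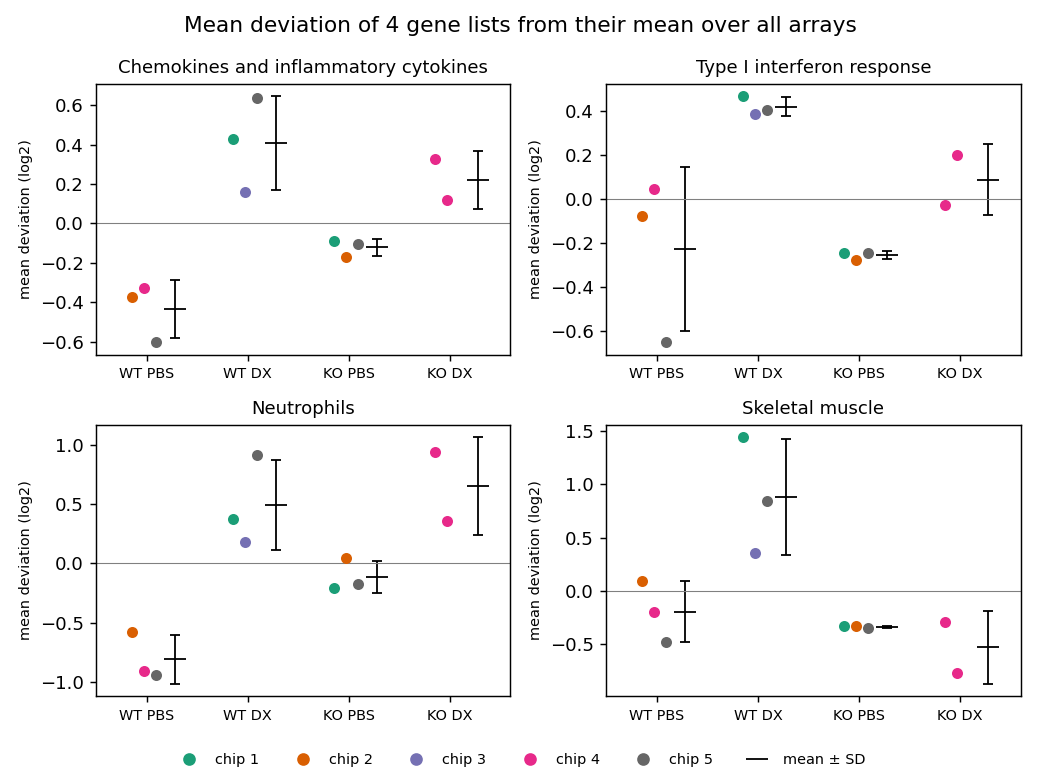
Mean log2 deviation (vertical) of 4 gene lists from their average over all arrays, 1 point per array coloured by chip, in the 4 groups (horizontal) with mean and SD. Neutrophil genes lay at -0.95 to -0.58 in WT PBS and -0.21 to 0.04 in KO PBS, and muscle genes reached 1.44 in WT DX.

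Without DX, Cxcl1 was the only gene that differed past the threshold between KO and WT hosts, higher in KO. The neutrophil and chemokine lists were also higher in KO with camera at its fixed correlation, but neither kept its call with an estimated correlation. Cxcl1 stood 1.34 higher in KO (SE 0.155, adjusted p = 0.0312), with limma means of 9.59 in WT PBS, 10.93 in KO PBS, 11.29 in WT DX and 11.27 in KO DX. At an unadjusted p under 0.05 there were 582 genes.

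Not past the threshold were S100a8 at 1.79 (adjusted p = 0.0604), Il24 (an interleukin 10 family cytokine) at 1.18 (adjusted p = 0.0604), S100a9 at 1.68 (adjusted p = 0.0814), Arg2 (mitochondrial arginase) at 1.5, Cxcl2 at 1.78 (adjusted p = 0.256) and Il1b at 1.01. Lower in KO, also not passing, were Mmrn1 (multimerin, of endothelium and platelets), at least 1.82-fold (adjusted p = 0.0598), Tpsab1 (mast cell tryptase), at least 7.76-fold (adjusted p = 0.206), Tef (a circadian transcription factor) at -0.88 and Itgbl1 (an integrin-like matrix protein) at -1.45. Of the lists 7 passed, all upward: neutrophils at a median of 0.57 (adjusted p = 0.382 with an estimated correlation), chemokines at 0.22 and extracellular matrix at 0.16 (both adjusted p = 0.475 with an estimated correlation), with Col1a1 (collagen) at 0.67. The others were monocytes at 0.16 (adjusted p = 0.724 with an estimated correlation), antigen presentation at 0.16 (adjusted p = 0.936 with an estimated correlation), immediate early genes at 0.11 (adjusted p = 0.251 with an estimated correlation) and B cells at 0.59 (adjusted p = 0.585 with an estimated correlation), where KO PBS 2 stood 1.63 above average. Within chips 2 and 5 neutrophils differed by 0.56 and 0.65, chemokines by 0.22 and 0.40, and antigen presentation by -0.20 and 0.52. Other splits of the arrays gave a median of 6 lists.

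Within chips 2 and 5 Cxcl1 differed by 0.96 and 1.65, S100a8 by 1.47 and 1.63 and Cxcl2 by 1.23 and 1.69. With the chip block Cxcl1 stood at 1.32 (adjusted p = 0.213) and 0 genes passed in limma, with 1001 at an unadjusted p under 0.05. The count was 0 without KO DX 1, KO DX 2, KO PBS 1, KO PBS 2, KO PBS 3, WT DX 1 or WT PBS 2, and 3 without WT DX 2 or WT DX 3, and without WT PBS 3 another gene passed in place of Cxcl1.

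After DX, skeletal muscle, interferon, antigen presentation and macrophage genes were lower in KO than in WT tumours as lists with camera at its fixed correlation, but no list passed with an estimated correlation and no gene passed. With the muscle gene mean as a covariate, chosen after the data had been seen, the medians turned to 0.46 for antigen presentation (camera adjusted p = 4.26e-05), 0.39 for monocytes, 0.015 for interferon, 0.19 for chemokines, 0.68 for NK cells (camera adjusted p = 0.000398), 0.40 for dendritic cells, 0.79 for mast cells and 0.57 for adipocytes. That covariate largely overlapped with the groups, so these turns do not show an opposite effect. The neutrophil list, at a median of 0.17, did not pass (adjusted p = 0.301). Limma gave 0 genes, with 712 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0509, and the chip block also gave 0. At that smallest value stood Fez1 (an axonal transport adaptor) at 1.30, Tcap (telethonin, of the sarcomere) at -2.32 and Mylpf at -1.95. The other kept probe stood at 0.84 for Fez1, -1.25 for Tcap and -2.14 for Mylpf. Myl1 stood at -1.77 and Clec2d at -1.33 (both adjusted p = 0.0643), Pgam2 (muscle phosphoglycerate mutase) at -1.83, Tpsab1 lower by at least 9.76-fold, Il24 at 1.01, Csta3 higher by at least 1.37-fold, Tapbp at -0.87 (its other kept probe at -0.38) and C1qa (a complement subunit of macrophages) at -0.71.

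Of the lists 9 passed in this comparison, all downward: skeletal muscle at a median of -1.62 (adjusted p = 0.22 with an estimated correlation), where 15 of 18 fell when adjusted over the list alone, and 8 more, each at adjusted p = 0.51 with an estimated correlation. These were interferon at -0.24, antigen presentation at -0.24, monocytes at -0.26, NK cells at -0.52, chemokines at -0.20, mast cells at -0.49, adipocytes at -0.48 and dendritic cells at -0.41. With the chip block 16 lists passed with camera, though of the other groups only WT PBS 2 shared a chip with the KO DX arrays. Leaving out WT DX 2 gave 38 genes, WT PBS 1 gave 7 and KO PBS 1 gave 1. Without 1 array the mast cell median ranged from -1.12 to 0.032.

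Averaged over both genotypes, some neutrophil, chemokine, interferon and p53 genes rose with DX, and Dlk1 and Tfrc fell. No list passed with an estimated correlation, while 5 of the 25 passed with fry. Of the genes, 57 passed, 54 rising and 3 falling, with 1233 at an unadjusted p under 0.05. Ppbp rose (adjusted p = 0.000145), by at least 18.1-fold in WT, its probe detected on no PBS array. Cxcl2 rose by 3.19, S100a9 by 2.36, Cstdc4 by 2.09 and S100a8 by 1.96 (adjusted p = 0.000847). Dlk1 fell by 1.36 (adjusted p = 0.00104), Tfrc by 0.77 and Mettl26 (a methyltransferase-like protein) by 0.51. Reg1 (a regenerating islet protein) at -2.23 did not pass (adjusted p = 0.059). Cdkn1a rose by 1.30, Ccl4 by 1.38, Ccl3 by 1.74, Cxcl1 by 1.01, Rsad2 by 0.95, Oasl1 by 1.01, Hdc by 1.54, Trp53inp1 by 0.86 and Krt16 by 1.24.

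Of the lists 9 passed for the averaged DX effect: chemokines at a median of 0.63 (8 rose, 22 adjusted over the list alone) and neutrophils at 0.96 (3 rose, 9 adjusted over the list alone), both at adjusted p = 0.102 with an estimated correlation. Interferon stood at 0.46 (2 rose, 25 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation), p53 targets at 0.08 (adjusted p = 0.05 with an estimated correlation), hypoxia at 0.14 (adjusted p = 0.602 with an estimated correlation) and red blood cells at -1.28 (adjusted p = 0.223 with an estimated correlation). Muscle stood at 0.49, keratinocytes at 0.64 and fibroblasts at -0.18, each at adjusted p = 0.3 with an estimated correlation. Other splits gave a median of 7 lists. With the chip block 17 genes passed, 12 of them shared, and hypoxia turned to -0.012 and lost its call. The count was 18 without KO DX 1, 37 without KO DX 2, 28 without KO PBS 1, 36 without KO PBS 2, 20 without KO PBS 3, 26 without WT DX 1, 130 without WT DX 2, 34 without WT DX 3 and 36 without WT PBS 3. Ppbp, Cxcl2, S100a9, Cstdc4, S100a8, Dlk1, Cdkn1a, Ccl4, Cxcl1 and Ccl3 passed in all 11 of these runs.

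Averaged over treatments, KO tumours had more Il24 and Fez1 and less Tpsab1 and Tcap. These were the only 4 genes past the threshold, with 767 at an unadjusted p under 0.05. Il24 rose by 1.09 and Fez1 by 0.94 (both adjusted p = 0.0249), while Tcap fell by 1.57 (adjusted p = 0.0371). The other kept probe stood at only -0.65 for Tcap and at 0.77 for Fez1. Tpsab1 fell (adjusted p = 0.0461), and as it was detected on 0 of 5 KO arrays its fall was at least 7.76-fold in PBS and 9.76-fold in DX. Myl1 at -1.18, Cirbp (a cold-inducible RNA-binding protein) at -0.74 (both adjusted p = 0.0615), Sis (sucrase-isomaltase) at -0.71, Arg2 at 1.08 and Cxcl1 at 0.66 (adjusted p = 0.0867) did not pass. Of the lists 4 passed: muscle at a median of -0.82 (adjusted p = 0.426 with an estimated correlation), neutrophils at 0.39 (adjusted p = 0.846 with an estimated correlation), and interferon at -0.16 and NK cells at -0.24 (both adjusted p = 0.887 with an estimated correlation). The NK median turned to 0.35 with the muscle covariate (camera adjusted p = 0.00398 at the fixed correlation), which largely overlapped with the groups. Other splits gave a median of 8 lists. With the chip block 14 lists passed with camera at its fixed correlation.

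With the chip block 0 genes passed for the averaged KO effect in limma (1116 at an unadjusted p under 0.05), Il24 at adjusted p = 0.176, Fez1 and Tpsab1 at adjusted p = 0.138 and Tcap at adjusted p = 0.09. The count of 4 was 0 without KO DX 1, KO DX 2, KO PBS 1, KO PBS 2, KO PBS 3 or WT PBS 2, 3 without WT DX 1, 15 without WT DX 2 and 1 without WT DX 3 or WT PBS 1.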

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

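The weighing of the muscle genes against a shared DX response, the interval described for the muscle covariate and the rule that 1 tying array decides nothing about the chip were chosen after results had been seen, while the other tests here had their outcomes written down first. In the authors' value table, replicate 2 of both WT groups equalled the mean of replicates 1 and 3 to within 7e-05 at every probe. Removal of a BeadChip term by a linear model holding the groups could give this, because the arrays of 1 chip were shifted by the same amount (median correlation of the shifts 1, against -0.138 for arrays on other chips, the highest of those 0.0866). That removal rebuilt the table with a median absolute difference of 5.17e-06 and a largest of 0.00715. A filling of only the 2 columns with averages was argued against, since the other 9 arrays were shifted as well, with a median SD of 0.108 (0.0862 to 0.189). The table spends degrees of freedom that a later test does not count, so it was used only as an alternative.

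Skeletal muscle genes stood higher in WT DX tumours than in the other groups. Muscle tissue taken with some samples may account for this, and the first component of the list held 0.608 of the variance within groups, which the limits set beforehand left undecided. A response to DX shared by both genotypes was argued against by the KO median of -0.202, beside 1.26 in WT, though that outcome was written after the values were known.

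Of the 25 lists, 15 were lower for the difference of DX effects, KO minus WT, with camera at its fixed correlation, and 0 passed with an estimated correlation or with fry. The medians of the gene differences were -0.5616 for T cells, -0.3918 for NK cells, -0.6777 for B cells, -0.4028 for dendritic cells, -0.4748 for monocytes, -0.4367 for neutrophils, -0.5047 for mast cells, -0.2079 for fibroblasts, -1.489 for muscle, -0.1569 for p53 targets, -0.2465 for interferon, -0.3827 for antigen presentation, -0.4797 for chemokines, -0.2425 for extracellular matrix and -0.3061 for immediate early genes. The BeadChip stays open as a source: the interferon difference was -0.8674 with the chip block, but only 1 array, WT PBS 2, ties the KO DX arrays to the other groups, and the outcome written beforehand as excluding the chip overlooked this. Among 100 splits of treatment within genotype, 4 gave as many lists, the real one included, and the highest other split gave 18. This met the outcome written beforehand against a random division. Such splits remove the DX effect itself along with its difference between genotypes, so they could not decide whether the difference arose by chance. The muscle share of the samples may be the source, since the interferon difference became 0.005636 with the muscle mean as a covariate, which meets the outcome written beforehand for such a source. A further rule, added after that median had been seen, asked for an interval of the list mean: it was -0.303 (SE 0.256, -0.909 to 0.302) without and -0.0776 (SE 0.394, -1.04 to 0.887) with the covariate. As 0.793 of the muscle mean's variance lay between groups, the covariate largely overlapped with the groups. The interval with the covariate held both 0 and the value without it, so the question was left undecided.

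Splits of the arrays were also counted for the other totals. For WT DX, 1 of 10 splits gave 66 genes or more (highest other 0) and 2 of 10 gave 14 lists or more (highest other 16). For KO minus WT in PBS it was 1 of 10 for genes (highest other 0) and 4 of 10 for lists (highest other 8), and 10 splits are too few for a share under 0.05. For DX averaged, 1 of 100 splits reached 57 genes (highest other 2), which argues against a random division, but 40 of 100 reached 9 lists (highest other 17). For KO averaged, 5 of 100 reached 4 genes (highest other 12) and 80 of 100 reached 4 lists (highest other 19), so a random division was not ruled out for either. Apart from the named genes, 6 of the 4181 kept probes without a single gene name passed in WT DX, 4 rising and 2 falling.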

How the results depend on the processing

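The muscle covariate, the removal of the Eif2s3y arrays, the authors' table without its averaged columns and the unsubtracted chip-block model were chosen after the data had been seen. Counts of genes past the threshold and the signs of some changes, not all of them small, depended on the processing, whereas the large changes of Ppbp, Cxcl2, S100a8, S100a9 and Cdkn1a in WT kept their sign in every setting. For each change of a result named here the cause was not tested. Not run were the level of Fpr1, within-chip differences for the KO DX contrasts and a list test under the random chip block. With an estimated correlation 67 of 68 list calls ended, with fry 58 did, and with the chip block 61 kept their call, 3 lost it and 4 had the opposite sign. No pairing of the samples by replicate number was seen. Arrays of the same number correlated at -0.291 to 0.304 after group means were removed (4 of 15 over 0.1) and arrays of other numbers at -0.304 to 0.272 (11 of 30 over 0.1). Deviations from a mean of so few arrays depend on each other, so these correlations cannot show that the samples were unpaired. With the replicate block limma gave 63 genes for WT DX, 0 for KO DX (486 unadjusted), 0 for the difference (443 unadjusted), 0 for KO minus WT in PBS (531 unadjusted), 5 for KO minus WT in DX, 45 for DX averaged and 6 for KO averaged.

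The main counts were 66 for WT DX, 0 for KO DX, 0 for the difference, 1 for KO minus WT in PBS, 0 for KO minus WT in DX, 57 for DX averaged and 4 for KO averaged. No background correction gave 8 for KO DX, 10 for KO minus WT in DX, 112 for DX averaged and 14 for KO averaged. Median scaling in place of quantile gave 19 for WT DX, 0 for KO minus WT in PBS (384 unadjusted), 25 for DX averaged and 0 for KO averaged (609 unadjusted). The stricter filter on dim probes gave 3 for KO minus WT in DX. The mean of the probes of a gene gave 2 for KO DX and 2 for KO averaged. Every kept probe on its own gave 1 for the difference, 2 for KO minus WT in PBS and 5 for KO minus WT in DX. Only the groups of the contrast gave 12 for WT DX, 1 for KO DX and 0 for KO minus WT in PBS (514 unadjusted). BeadChip as a fixed block gave 1 for KO DX, 0 for KO minus WT in PBS (1001 unadjusted), 17 for DX averaged and 0 for KO averaged (1116 unadjusted), and as a random block (correlation 0.132) 2 for KO minus WT in PBS. Array weights (0.338 for WT PBS 1 to 2.7 for WT DX 1) gave 363 for WT DX, 28 for KO DX, 2 for the difference, 136 for KO minus WT in DX, 338 for DX averaged and 39 for KO averaged. Trend and robust empirical Bayes gave 116 for WT DX, 6 for KO DX, 2 for the difference, 4 for KO minus WT in PBS, 9 for KO minus WT in DX, 116 for DX averaged and 19 for KO averaged.

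The authors' value table gave 5532 for WT DX, 5153 for KO DX, 6001 for the difference, 2601 for KO minus WT in PBS, 6013 for KO minus WT in DX, 4634 for DX averaged and 3509 for KO averaged. Without the averaged columns it gave 2795, 3755, 4124, 433, 4283, 2360 and 1256 in the same order. No background correction with BeadChip as a fixed block on the value table probes gave 365, 1, 3, 7, 4, 240 and 21. The muscle gene mean as a covariate gave 0 for WT DX (589 unadjusted), 2 for KO minus WT in PBS, 14 for DX averaged and 0 for KO averaged (507 unadjusted). Without the arrays with Eif2s3y signal there were 35 for KO minus WT in DX and 24 for KO averaged. Leaving out WT DX 3 gave 10 for WT DX. Leaving out WT DX 2 gave 233 for WT DX, 3 for KO minus WT in PBS, 38 for KO minus WT in DX, 130 for DX averaged and 15 for KO averaged. Leaving out KO DX 1 gave 0 for KO DX (308 unadjusted), 0 for the difference (406 unadjusted), 0 for KO minus WT in PBS (500 unadjusted), 0 for KO minus WT in DX (460 unadjusted), 18 for DX averaged and 0 for KO averaged (484 unadjusted). KO DX gave 2 without KO DX 2, and the difference gave 1 without KO PBS 1.

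With the muscle gene mean as a covariate, an alternative chosen after the data had been seen, these log2 changes and list medians had the opposite sign. The covariate largely overlapped with the groups. Klra3 at -0.35, Klrk1 at -0.39, Klrb1c at -0.29, Cd163 at -0.019, Fcer1a at -0.50 and Mcpt4 at -0.37 turned in WT DX minus PBS. Cma1 at -0.60, Plin4 at -0.46, Tgtp1 at -0.14, Mdm2 at -0.14 and Ifng at -1.13 turned in WT DX minus PBS. Icos at 0.17, Cd6 at 1.02, Cd2 at 0.61, Cd3g at 1.44, Klra3 at 0.18, Klrk1 at 0.28, Fasl at 0.93, Ccl17 at 0.21 and Cd209a at 0.36 turned in the difference of DX effects. Cma1 at 0.46, Cpa3 at 1.17, Cd74 at 0.046, Egr2 at 0.18, Cdkn1a at 0.10, Mdm2 at 0.46, Cd3e at 1.63 and Ifng at 1.45 turned in the difference of DX effects. Klra3 at 0.16, Klre1 at 0.34, Klrd1 at 0.56, Cd209a at 0.38, Ccl17 at 0.42, Cd163 at 0.90, Mrc1 at 0.49, Mcpt4 at 0.79, Tpsb2 at 0.75 and Car3 at 0.21 turned in KO minus WT in DX. Adipoq at 0.34, Lpl at 1.47, Lep at 0.80, Zbp1 at 0.26, Psmb8 at 0.0031, Ccl6 at 0.21, Cxcl16 at 0.31, Cd3e at 1.97 and Cxcl10 at 0.011 turned in KO minus WT in DX. Ifng at -0.41 turned in DX minus PBS averaged. Klre1 at 0.10, Klra3 at 0.069, Klrd1 at 0.16, Nkg7 at 0.60, Fpr2 at 0.025, Cd3e at 1.15 and Cxcl10 at 0.19 turned in KO minus WT averaged. Cytotoxic and NK cells at -0.70, Monocytes and macrophages at -0.046, Mast cells and basophils at -0.50, Adipocytes at -0.019 and Antigen presentation and interferon gamma response at -0.17 turned in WT DX minus PBS. T cells at 0.73, Cytotoxic and NK cells at 0.86, Dendritic cells at 0.28, Monocytes and macrophages at 0.034, Mast cells and basophils at 0.47, p53 targets at 0.042, Type I interferon response at 0.0056 and Antigen presentation and interferon gamma response at 0.20 turned in the difference of DX effects. Cytotoxic and NK cells at 0.68, Dendritic cells at 0.40, Monocytes and macrophages at 0.39, Mast cells and basophils at 0.79, Adipocytes at 0.57, Type I interferon response at 0.015, Antigen presentation and interferon gamma response at 0.46 and Chemokines and inflammatory cytokines at 0.19 turned in KO minus WT in DX. Cytotoxic and NK cells at 0.35 turned in KO minus WT averaged.

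With no background correction 1 gene had the opposite sign. Cd3e at 0.020 turned in WT DX minus PBS.

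With the authors' value table, with that table without the averaged columns, and with no background correction with BeadChip as a fixed block on the value table probes, the same values turned, and their first digits were the same. The last 2 of these settings were added after the data had been seen. Ifng was at -0.0013 in KO minus WT averaged with the last of the 3. Cd3e at 0.68 turned in WT DX minus PBS. Itgax at -0.14, Cxcl10 at -0.48 and Ccl2 at -0.63 turned in KO DX minus PBS. Mdm2 at 0.42 and Itgax at -0.089 turned in the difference of DX effects. Mdm2 at -0.091 turned in KO minus WT in PBS. Ifng at -0.17 and Itgax at -0.093 turned in KO minus WT in DX. Cd3e at 0.15 turned in DX minus PBS averaged. Ifng at -0.0014 and Itgax at -0.049 turned in KO minus WT averaged. Hypoxia and glycolysis at -0.015 turned in WT DX minus PBS. Type I interferon response at -0.00035 and Hypoxia and glycolysis at -0.040 turned in KO DX minus PBS. Hypoxia and glycolysis at -0.011 turned in DX minus PBS averaged.

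With the BeadChip as a fixed block these values had the opposite sign. Cd3e at 1.00 turned in WT DX minus PBS. Itgax at -0.43, Cxcl10 at -0.49 and Ccl2 at -0.64 turned in KO DX minus PBS. Mdm2 at 0.46 and Itgax at -0.27 turned in the difference of DX effects. Mdm2 at -0.10 turned in KO minus WT in PBS. Ifng at -0.37 and Itgax at -0.27 turned in KO minus WT in DX. Cd3e at 0.17 turned in DX minus PBS averaged. Itgax at -0.14 turned in KO minus WT averaged. Hypoxia and glycolysis at -0.016 turned in WT DX minus PBS. Type I interferon response at -0.021 and Hypoxia and glycolysis at -0.020 turned in KO DX minus PBS. Hypoxia and glycolysis at -0.012 turned in DX minus PBS averaged.

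With the BeadChip as a random block fewer values had the opposite sign. Cd3e at 0.058 turned in WT DX minus PBS. Itgax at -0.013 and Ccl2 at -0.045 turned in KO DX minus PBS. Mdm2 at 0.037 turned in the difference of DX effects.

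Array weights turned these genes. Cd3e at 0.57 turned in WT DX minus PBS. Ccl2 at -0.00057 turned in KO DX minus PBS. Mdm2 at -0.021 and Itgax at -0.041 turned in KO minus WT in DX. Cd3e at 0.0093 turned in DX minus PBS averaged. Fpr2 at 0.082, Itgax at -0.10 and Cxcl10 at 0.12 turned in KO minus WT averaged.

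Without the arrays with Eif2s3y signal (WT DX 2 and WT PBS 3), left out after the data had been seen, these had the opposite sign. Cd3e at 0.29 and Itgax at 0.025 turned in WT DX minus PBS. Anxa1 at -0.011 turned in the difference of DX effects. Cd3e at -0.21 and Itgax at 0.0090 turned in KO minus WT in PBS. Mdm2 at -0.083 and Ifng at -0.34 turned in KO minus WT in DX. Itgax at 0.034 turned in DX minus PBS averaged. Mdm2 at -0.023 and Ifng at -0.062 turned in KO minus WT averaged. Hypoxia and glycolysis at -0.11 turned in WT DX minus PBS.

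With the mean of the probes of a gene 2 values turned. Ifng at -0.0031 turned in KO DX minus PBS. Mdm2 at -0.021 turned in KO minus WT in DX.

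With median scaling in place of quantile normalization 4 values turned. Itgax at -0.024 and Ccl2 at -0.00030 turned in KO DX minus PBS. Fcrla at -0.075 turned in KO minus WT in PBS. Itgax at -0.11 turned in KO minus WT averaged.

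Of the lists past the threshold, 1 had the opposite sign within chip 2. Antigen presentation and interferon gamma response at -0.20 turned in KO minus WT in PBS. Genes and lists not past the threshold also differed in sign from the main value within a chip. In KO minus WT in PBS these were, within chip 2, Irf1 at -0.083, Tapbp at -0.20, Cd274 at -0.43, Atf3 at -0.030, Fpr2 at -0.32, Mdm2 at -0.34, Cd3e at -0.0043, Ifng at -0.20 and Itgax at 0.30. Within chip 5 they were Fcrla at -0.24 and Cdkn1a at 0.070, and in WT DX minus PBS Anxa1 at 0.12 and Cd3e at 1.29. Among lists, chip 5 gave fibroblasts 0.18, histones 0.15 and B cells 0.0042 in WT DX minus PBS. For KO minus WT in PBS, chip 2 gave dendritic cells 0.13, fibroblasts -0.012, formyl peptide receptors -0.21 and hypoxia -0.27. Chip 5 gave NK cells 0.10, dendritic cells 0.058, adipocytes 0.20, muscle 0.10, interferon 0.44, cell cycle -0.18, histones 0.0079 and the unfolded protein response -0.0076 there.

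Leaving out 1 array at a time gave these genes and lists values on both sides of 0, given as the lowest and highest of the runs. Anxa1 from -0.20 (without WT DX 3) to 0.0021 (without WT DX 2), Cd3e from -0.39 (without WT DX 3) to 0.60 (without WT DX 2) and Ifng from -0.16 (without WT DX 3) to 0.80 (without WT DX 2) spanned 0 in WT DX minus PBS. Fpr2 from -0.17 (without KO DX 1) to 0.36 (without KO DX 2), Anxa1 from -0.21 (without KO PBS 2) to 0.18 (without KO PBS 1), Ifng from -0.26 (without KO DX 1) to 0.41 (without KO DX 2), Itgax from -0.070 (without KO DX 2) to 0.16 (without KO DX 1) and Ccl2 from -0.13 (without KO DX 2) to 0.19 (without KO DX 1) spanned 0 in KO DX minus PBS. Fcrla from -0.86 (without KO PBS 1) to 0.11 (without KO PBS 2), Anxa1 from -0.11 (without KO PBS 2) to 0.28 (without KO PBS 1), Mdm2 from -0.22 (without WT PBS 1) to 0.15 (without WT PBS 2) and Ifng from -0.73 (without WT DX 2) to 0.23 (without WT DX 3) spanned 0 in the difference of DX effects. Fcrla from -0.46 (without KO PBS 2) to 0.51 (without KO PBS 1), Mdm2 from -0.12 (without WT PBS 2) to 0.24 (without WT PBS 1), Cd3e from -0.21 (without WT PBS 3) to 0.43 (without WT PBS 1), Itgax from -0.34 (without WT PBS 1) to 0.15 (without WT PBS 2) and Ccl2 from -0.024 (without WT PBS 1) to 0.46 (without WT PBS 2) spanned 0 in KO minus WT in PBS. Tpsb2 from -1.25 (without KO DX 1) to 0.062 (without KO DX 2), Lpl from -1.30 (without KO DX 1) to 0.22 (without KO DX 2), Mdm2 from -0.094 (without KO DX 1) to 0.15 (without KO DX 2), Ifng from -0.34 (without WT DX 2) to 0.62 (without WT DX 3) and S100a8 from -0.071 (without KO DX 1) to 0.58 (without KO DX 2) spanned 0 in KO minus WT in DX. Anxa1 from -0.16 (without KO PBS 2) to 0.038 (without KO PBS 1), Ifng from -0.044 (without WT DX 3) to 0.44 (without WT DX 2) and Itgax from -0.23 (without WT PBS 1) to 0.012 (without WT PBS 2) spanned 0 in DX minus PBS averaged. Fpr2 from -0.24 (without KO DX 1) to 0.062 (without WT DX 3), Mdm2 from -0.047 (without WT PBS 2) to 0.14 (without WT PBS 1), Cd3e from -0.54 (without WT DX 2) to 0.033 (without KO DX 2), Itgax from -0.065 (without WT PBS 1) to 0.19 (without WT DX 1), Cxcl10 from -0.15 (without WT PBS 3) to 0.087 (without WT PBS 2) and Ccl2 from -0.18 (without WT PBS 1) to 0.063 (without WT PBS 2) spanned 0 in KO minus WT averaged. Hypoxia and glycolysis from -0.018 (without WT PBS 3) to 0.22 (without WT PBS 2) spanned 0 in WT DX minus PBS. Hypoxia and glycolysis from -0.0020 (without KO PBS 2) to 0.18 (without KO PBS 1) spanned 0 in KO DX minus PBS. Mast cells and basophils from -1.12 (without WT DX 2) to 0.032 (without WT DX 3) spanned 0 in KO minus WT in DX.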

Other observations

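The genes and comparisons in this part were picked after their values had been seen, except the test of the genes next to Fpr1, whose outcomes were written first. Beside the genes named by rule, DX in WT hosts raised Ifnb1 (interferon beta) by 1.54 (adjusted p = 0.0347), Il1b by 1.28 (adjusted p = 0.0319), Clec2d by 1.56 (adjusted p = 0.00292), Arg2 by 1.5, Mmp12 (macrophage elastase) by 1.37, Siglec1 (a sialic acid receptor of macrophages) by 1.18, Il1r2 (the decoy receptor of interleukin 1) by 1.16 and Csf2 (a myeloid growth factor) by 0.73.

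The baseline of KO tumours may bear on the smaller DX change there. Cxcl1, S100a8 and Cxcl2 stood at 9.59, 7.51 and 6.00 in WT PBS but at 10.93, 9.31 and 7.78 in KO PBS, whereas after DX the levels were 11.29, 10.24 and 9.79 in WT and 11.27, 10.49 and 10.37 in KO. For these 3 genes the KO and WT levels lay farther apart before DX than after it. The difference of DX effects is built from these same group means, so the higher start restates it and does not explain it. All 3 were called in WT, which favours genes with low WT PBS values. The probe of Ppbp was not detected on any PBS array, so it has no start level to compare. The higher start itself was not secure, since Cxcl1 lost its call with the chip block, at 1.32 (adjusted p = 0.213). Its size there was close to that without the block, and the block left only 3 residual degrees of freedom. A test would be to inject PBS and DX in more hosts of both genotypes on the same chips.

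Tpsab1 was detected on 6 of 6 WT arrays and 0 of 5 KO arrays, with group means of 8.37 in WT PBS, 8.60 in WT DX, 4.79 in KO PBS and 5.20 in KO DX. The median of the mast cell list as a whole was not past the threshold for the averaged KO effect. A segment of another strain around the targeted gene could set KO apart from WT near Fpr1. The 31 measured genes within 5 Mb of Fpr1 had a mean squared t of 2.26 (random sets 1.4), at percentile 92.5, which left this undecided, and 0 of them passed. Tpsab1 lay outside that window, and as no wider one was tested, such a segment stays open for Tpsab1 as well.

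Eif2s3y, a gene of the Y chromosome, read 8.53 in WT DX 2 and 8.52 in WT PBS 3 and 4.41 to 4.94 on the other arrays, while Xist was high on all 11 (10.8 to 11.7). Some male cells may have been present in these 2 samples, from host or tumour. Without both arrays WT DX gave 64 genes, 27 of them among the 66, and KO minus WT in DX gave 35, and what set these arrays apart was not tested.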
